A study of Homo sapiens with 3 samples.

How the data were processed

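Poly-A RNA of CAMA1 breast cancer cells was sequenced in 3 libraries of 1 group, described as biological replicates, from cells held for 48 h in medium lacking estradiol. Per the labels' protocols, libraries were prepared with a stranded Illumina mRNA kit from RNA that had passed a quality check, and were sequenced on a NextSeq 500. The values were expected counts per gene as deposited by the authors: they need not be whole, and 83.1 ± 0.243% of non-zero values per library were whole within 1e-08 (SD, n = 3). Per the submitters' processing notes, TopHat, Subread and featureCounts were used with hg38; versions and settings, including how reads with several matches and strand were handled, were not given in the sources used here. The fractional values show that some reads were divided between features, so genes with near-identical copies, and genes that overlap others on either strand, are uncertain. The table also gave a length per gene, and all its value columns were used. The labels do not say whether the replicates were grown or sequenced together, so tests between them measure the spread of these libraries alone.

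The table held 26485 entries, of which 23758 matched an annotated gene by their own symbol, 1536 by an older symbol and 1191 not at all; 18981 were protein-coding. Of the 26485 entries, 1205 lay on several sequences and, counted separately, 1141 had a position on an alternate contig. The deposited length of 742 protein-coding genes was over 1.5 times their exon length on the main chromosome. Names of 28 entries had been turned into dates, among them 4 entries with a duplicated name, and these could not be matched to genes. Of 391 members of 29 gene lists 378 were found, and the other 13 were the mitochondrially encoded genes. Coordinates are 1-based positions on hg38.

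Totals per library were 26473939, 26592335 and 30745412 counts. A count of 0 leaves room for up to 3 counts, and members of a list with at most 3 counts in each library were called not detected. Levels are TPM from the deposited counts and lengths. A gene was called detected with at least 10 counts in each library. Ratios of receptors were formed within each library as log2 with 0.01 TPM added and tested with the exact two-sided sign-flip permutation test, whose smallest p with 3 libraries is 0.25. The level of a list was the median of log2(TPM + 1), averaged over libraries and set against 10000 random lists of as many protein-coding genes (two-sided). Luminal and basal lists were compared by 100000 permutations of membership (two-sided). Runs of consecutive protein-coding genes around FGFR1, CCND1 and ERBB2 were set against all runs of as many genes on the autosomes and X, which overlap one another and give a share and not a p-value.

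For the spread between replicates, counts were rounded to whole numbers and analysed in edgeR with TMM scaling (factors 1.01, 1.00 and 0.990), its filter on low counts and a design with an intercept only. Each gene was tested for variation beyond Poisson sampling with a chi-square test, and, as an alternative, beyond the trended negative binomial dispersion. Deviations of gene lists used log2 CPM with a prior count of 2, and the range over libraries was set against 10000 random lists matched on mean expression in 20 bins (one-sided), for lists with at least 3 tested members. Benjamini-Hochberg adjustment was made within each family at a threshold of 0.05, over genes, over the 27 lists tested for level or over the 26 lists tested for deviation.

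The lists covered FGF receptors, FGF ligands, FGFR signalling partners, MAPK output and feedback, estrogen response, luminal and basal epithelium, mesenchymal cells and fibroblasts, immune cells, endothelium, adipocytes, ERBB receptors, other receptor tyrosine kinases, nuclear receptors, RNA polymerase II and coactivators, nuclear import, proliferation, G1 regulators, interferon response, unfolded protein and amino acid stress, heat shock, hypoxia, cholesterol and lipid synthesis, housekeeping, mitochondrially encoded genes, small nuclear and 7SK/7SL RNA, and the 8p12-p11, 11q13 and 17q12 neighbourhoods. Lists, tests and the first set of alternatives were fixed before the data were examined. The genes named in the text were set by a rule fixed at the same time: the 5 FGF receptors with ESR1, PGR, ERBB2 and ESR2, the 10 protein-coding genes with the highest TPM, the 4 highest members of each list, markers of other cell types at 10 TPM or above, the 6 highest genes of each neighbourhood, and the 10 genes with the largest variation between replicates among those with a mean of at least 10 CPM. Some genes that the rule or an added list takes, and 1 added list, which passed its test, are not reported here. Genes named beyond that rule were chosen after their values were seen.

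The alternatives were count minimums of 1 and 20 or a mean of 1 TPM, CPM in place of TPM, another pseudocount (1 TPM for ratios, 0.1 for lists), a background or runs of detected genes only, the mean of a run, the median of a list, DESeq2 size factors, no filter on low counts and each replicate left out. Alternatives chosen after seeing the data were exon lengths on the main chromosome, genes with whole counts, removal of a smooth trend with GC content and length (loess span 0.5, with GC content known for 13938 of 14453 genes), leaving out the genes past the negative binomial test, and leaving EGR1 and FOS out of the MAPK list.

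The tests were tested on simulated data with known answers. For the spread between 3 libraries with 200 changed genes among 14319, the Poisson test called 79.1% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 93.9% of those changed 4-fold, and 11 of 14124 unchanged genes. On 14271 genes the negative binomial test called 20.9%, 68.7% and 95.5% of these and 2 of 14075 unchanged genes. With a simulated median coefficient of variation of 8.55% on 14271 genes, the common estimate was 8.61% with no gene changed and 10.9% with 200 genes changed, so changed genes raise it. The test of list deviations called 100 of 100 lists moved by 0.5 log2 units and 4 of 100 unmoved lists, also on 14271 genes. Genes were simulated independently and lists were random, so this share of false calls does not cover lists whose members vary together.

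Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0. Genes of the sex chromosomes that mark sex, DNA copy number and any treated samples were not analysed here.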

Results

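Messenger RNA was profiled in CAMA1, an established human breast cancer cell line that expresses the estrogen receptor and is described as FGFR1-amplified. The cells were kept for 48 h in medium without estradiol before RNA was taken. The series holds 1 group of 3 libraries, described as biological replicates, and no treated group. The deposited counts summed to 26473939, 26592335 and 30745412 in replicates 1, 2 and 3. The questions that this design allows were which genes and gene groups these cells expressed, how the FGF receptors and hormone receptors stood to one another, how the chromosomal surroundings of FGFR1 were expressed, and how far the replicates differed. All errors of levels are SD over libraries (n = 3), and intervals or limits drawn from counts cover counting error only.

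The highest transcripts of CAMA1 cells came from genes of the cytoskeleton, calcium and lipid binding, and the ribosome. S100A6, a calcium-binding protein gene, stood highest at 8580.4 ± 919 TPM, the transcript share after scaling by gene length and library total, followed by ACTB at 8347 ± 509 TPM and TMSB4X, whose product binds actin monomers, at 8143 ± 1111 TPM. FABP7, a fatty acid-binding protein gene, reached 6124 ± 1244 TPM. MYL6 at 5033 ± 81.0 TPM, ACTG1 at 4047 ± 238 TPM and the galectin gene LGALS1 at 3946 ± 280 TPM were also among the 10 highest, as were the ribosomal protein genes RPS27 (4815 ± 337 TPM), RPL41 (4802 ± 158 TPM) and RPS14 (4331 ± 58.0 TPM). The actin and ribosomal protein genes have near-identical copies elsewhere in the genome, so their levels are uncertain.

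In all, 14529 genes, of which 12783 were protein-coding, had at least 10 counts in each library. Protein-coding genes held 95.6 ± 0.209% of counts. The 86 ribosomal protein genes took 4.06 ± 0.129%, the 64 replication-dependent histone genes 0.0607 ± 0.00265%, and the nuclear noncoding RNAs MALAT1 and NEAT1 together 1.09 ± 0.114%. The 10 genes with the most counts in each library, a ranking without division by length, held 4.23 ± 0.118% of counts, and the 100 with the most counts 14.8 ± 0.134%. None of the 13 mitochondrially encoded protein genes had a value in the table used here.

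FGFR4 was the most abundant FGF receptor transcript in CAMA1 cells, ahead of FGFR1, the receptor gene described as amplified in this line. FGFR4 (chromosome 5, 177086872 to 177098142) reached 1034 ± 267 TPM and FGFR1 (chromosome 8, 38411138 to 38468834) 88.0 ± 3.86 TPM, so that FGFR4 made up 89.5 ± 1.97% and FGFR1 7.86 ± 1.39% of the TPM of the 5 receptor genes. FGFR1 exceeded FGFR2 (2.59 ± 0.878 TPM) 35.4-fold, FGFR3 (4.53 ± 0.0981 TPM) 19.4-fold and FGFRL1, which lacks a kinase domain (21.9 ± 2.14 TPM), 4.03-fold. FGFR1 ranked 2240 among protein-coding genes and FGFR4 ranked 102.

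The log2 ratio of FGFR1 was 5.15 ± 0.62 over FGFR2, 4.28 ± 0.07 over FGFR3, 2.01 ± 0.18 over FGFRL1 and −3.53 ± 0.30 over FGFR4 (SD, n = 3), each with the same sign in 3 of 3 libraries. The exact two-sided sign-flip permutation p was 0.25 for each ratio, the smallest that 3 libraries can give, so no ratio could pass 0.05. FGFR1 rested on 5461, 5312 and 6816 counts and FGFR4 on 27364, 28820 and 50520 counts in replicates 1 to 3. FGFR2 (chromosome 10, 121478330 to 121598458) had 167, 176 and 103 counts, FGFR3 (chromosome 4, 1793312 to 1808872) 204, 198 and 233, and FGFRL1 lies on chromosome 4 (1011822 to 1026898). FGFR4 itself differed between libraries, at 1024, 1085 and 1662 CPM, counts scaled by library totals with TMM factors (edgeR negative binomial adjusted p = 0.00176). Without division by gene length the log2 ratio of FGFR1 over FGFR4 was −2.55, that over FGFR3 4.78 and that over FGFRL1 2.97.

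**Figure D1:**
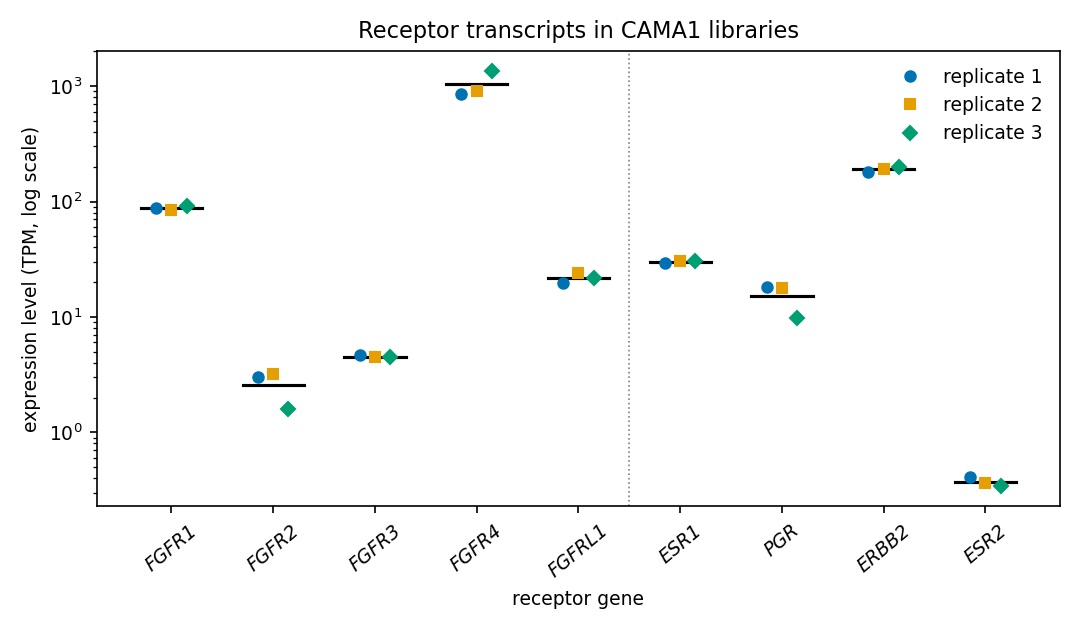
Levels of the FGF receptor genes and of ESR1, PGR, ERBB2 and ESR2 in TPM on a log axis, with a point for each of the 3 libraries and a black line for their mean. FGFR4 lay at 1034 TPM and FGFR1 at 88.0 TPM, while ESR2 lay at 0.373 TPM.

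Genes of the FGF ligand list, most of which code for growth factors that bind these receptors, were barely expressed. The 22 genes of this list had a median of 0.0111 TPM against 8.07 TPM over 18981 protein-coding genes. Of them 6 reached 10 counts in each library, and 13 had at most 3 counts in every library and were not detected. The 6 include FGF11, FGF12 and FGF13, intracellular members of the family, so they do not count secreted ligands alone. The highest of the list were FGF13 at 5.97 ± 0.239 TPM, FGF5 at 4.0 ± 0.357 TPM, FGF7 at 3.91 ± 0.539 TPM and FGF22 at 2.10 ± 0.469 TPM. Of the 11 genes of FGFR signalling partners 10 were detected, with the adaptor genes GRB2 at 161 ± 1.24 TPM and SHC1 at 108 ± 7.61 TPM, the phosphatase gene PTPN11 at 159 ± 6.93 TPM and PLCG1 at 78.0 ± 4.96 TPM. Of the 15 genes of MAPK output and feedback 10 were detected, with CCND1 at 263 ± 5.83 TPM and SPRED2 at 44.2 ± 1.35 TPM. EGR1, at 16.7, 395 and 402 TPM in replicates 1, 2 and 3, and FOS, at 5.05, 99.2 and 77.4 TPM, were below both in replicate 1.

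The ligand list lay below random lists of protein-coding genes (adjusted permutation p = 0.0018). The receptor list (median 21.9 TPM, adjusted permutation p = 0.587), the partner list (26.9 TPM, 0.289) and the MAPK list (3.45 TPM, 0.65) did not pass the test. Against detected genes only, the ligand list no longer passed (adjusted permutation p = 0.0567), and on CPM the partner list passed (0.0227). These p-values compare lists of genes within these libraries, and genes are not independent replicates.

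ESR1, the estrogen receptor gene, was expressed at 30.1 ± 0.665 TPM and lay below ERBB2, a growth factor receptor gene. ERBB2 stood at 191 ± 9.07 TPM and the progesterone receptor gene PGR at 15.2 ± 4.71 TPM, while ESR2 had 21, 19 and 21 counts (0.373 ± 0.0324 TPM). The log2 ratio of ESR1 was 6.30 ± 0.15 over ESR2, 1.04 ± 0.51 over PGR and −2.67 ± 0.05 over ERBB2 (SD, n = 3). The 3 ratios kept their sign in 3 of 3 libraries, with an exact two-sided sign-flip permutation p of 0.25, again the smallest possible. PGR was uneven between libraries, with 2322, 2328 and 1496 counts. Without division by length, the log2 ratio of ESR1 over PGR was 0.14 and its sign was not the same in all libraries. On hg38, ESR1 spans 151690496 to 152103273 on chromosome 6, PGR 101029624 to 101129813 on chromosome 11 and ERBB2 39688084 to 39728662 on chromosome 17.

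Estrogen response genes were mostly detected after 48 h without estradiol, 25 of 28, with a median of 18.9 TPM (adjusted permutation p = 0.292, not passing). XBP1, a transcription factor gene, stood at 1524 ± 135 TPM, SLC9A3R1 at 607 ± 82.4 TPM, the carbonic anhydrase gene CA12 at 407 ± 48.0 TPM and the cathepsin gene CTSD at 254 ± 21.9 TPM. Among nuclear receptors (median 31.4 TPM, adjusted permutation p = 0.175), RXRA stood at 89.2 ± 10.4 TPM, NR2F6 at 78.3 ± 3.50 TPM and the retinoic acid receptor gene RARA at 56.0 ± 0.734 TPM. Of the ERBB receptors (median 110 TPM, adjusted permutation p = 0.101), ERBB3 stood at 238 ± 9.97 TPM and ERBB4 at 29.3 ± 1.60 TPM, whereas EGFR had 1, 0 and 0 counts and was not detectable at this depth. On CPM the ERBB list passed (adjusted permutation p = 0.0066). Other receptor tyrosine kinases had a median of 0.651 TPM (adjusted permutation p = 0.236, and 0.0393 against detected genes only), with EPHB4 at 140 ± 5.40 TPM, INSR at 8.03 ± 0.307 TPM and EPHA2 at 7.39 ± 1.13 TPM. DDR1 stood at 87.4 ± 6.67 TPM with the deposited length and at 456 TPM with its exon length on the main chromosome, an alternative chosen after seeing the data.

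CAMA1 cells carried a strong luminal epithelial profile. The 16 luminal genes were all at 10 TPM or above, with a median of 544 TPM, led by the keratin genes KRT19 (3256 ± 605 TPM), KRT8 (2470 ± 140 TPM) and KRT7 (1810 ± 103 TPM), next to XBP1. The 16 basal genes had a median of 1.08 TPM, and 5 of them reached 10 TPM: the contractile genes ACTG2 (43.2 ± 5.35 TPM), MYLK (31.8 ± 0.0968 TPM) and ACTA2 (31.7 ± 3.32 TPM), the keratin gene KRT16 (25.6 ± 2.32 TPM) and the cadherin gene CDH3 (12.8 ± 1.95 TPM). Luminal exceeded basal genes by 8.06 ± 0.20 on the log2(TPM + 1) scale (SD, n = 3; higher in 3 of 3 libraries; two-sided permutation p = 3e-05 from 100000 reassignments of genes to lists). The luminal list lay above random lists (adjusted permutation p = 0.0018) and the basal list did not pass (0.296).

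Markers of other cell types were low with few exceptions. COL3A1, a fibrillar collagen gene, stood at 163 ± 23.4 TPM on 9291, 9984 and 8850 counts, and COL1A1 at 10.5 ± 0.270 TPM; the 18 mesenchymal and fibroblast genes had a median of 0.0882 TPM, 6 were detected and 8 had at most 3 counts in each library. TWIST1 at 9.87 ± 0.164 TPM and VIM at 3.27 ± 0.0515 TPM were next. No immune, endothelial or adipocyte marker reached 10 TPM: the highest were LYZ at 6.48 ± 1.17 TPM, CD68 at 3.08 ± 0.470 TPM, CD8A at 1.54 ± 0.260 TPM and NKG7 at 1.18 ± 0.677 TPM among immune genes, VWF at 0.103 ± 0.0389 TPM among endothelial genes and PLIN1 at 0.839 ± 0.115 TPM among adipocyte genes. The mesenchymal list lay below random lists (adjusted permutation p = 0.0410), and the immune (0.193 TPM, 0.152), endothelial (0.0355 TPM, 0.0771, and 0.0457 without replicate 1) and adipocyte (0.0654 TPM, 0.236) lists did not pass. Against detected genes only, or on CPM, the mesenchymal list did not pass either.

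Genes of the transcription machinery and of nuclear import, the route by which large proteins enter the nucleus, were highly expressed. The 18 genes of RNA polymerase II and its coactivators were all at 10 TPM or above, with a median of 53.3 TPM (adjusted permutation p = 0.0101); POLR2B stood at 129 ± 7.58 TPM, POLR2C at 124 ± 2.67 TPM, POLR2E at 93.2 ± 2.40 TPM and POLR2A at 80.7 ± 2.52 TPM. The 13 nuclear import genes had a median of 61.9 TPM (adjusted permutation p = 0.0174), with RAN at 283 ± 13.9 TPM and the transport receptor genes KPNB1 at 258 ± 24.4 TPM, KPNA2 at 144 ± 10.5 TPM and IPO7 at 129 ± 4.28 TPM. Set against detected genes only, neither list passed.

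The heat shock, cholesterol and lipid synthesis, and hypoxia lists stood high as well. Heat shock genes had a median of 160 TPM (adjusted permutation p = 0.0018), with HSPA8 at 986 ± 18.4 TPM, HSP90AA1 at 732 ± 17.5 TPM, HSPD1 at 407 ± 31 TPM and DNAJB1 at 183 ± 12.1 TPM. With exon lengths on the main chromosome, chosen after seeing the data, that median was 395 TPM, as the near-identical genes HSPA1A and HSPA1B went from 159.9 to 775 and from 121 to 586 TPM. The 16 genes of cholesterol and lipid synthesis had a median of 106 TPM (adjusted permutation p = 0.0018), with the desaturase gene SCD at 379 ± 25.3 TPM, FASN at 274 ± 37.2 TPM, IDI1 at 244 ± 8.45 TPM and SQLE at 219 ± 30.2 TPM. Hypoxia genes had a median of 88.6 TPM (adjusted permutation p = 0.00386, and not passing on CPM). The glycolytic genes LDHA and PGK1 stood at 521 ± 10.1 and 494 ± 3.78 TPM, NDRG1 at 151 ± 50.9 TPM and the glucose transporter gene SLC2A1 at 138 ± 32.3 TPM. PGK1 is also in the housekeeping list. Of the 11 hypoxia genes 8 reached 10 TPM, while CA9 had 2, 0 and 2 counts. List levels in 1 group do not show whether the cells were stressed or hypoxic. Housekeeping genes, included as a reference, had a median of 447 TPM (adjusted permutation p = 0.0018), with ACTB highest, then GAPDH at 2030.4 ± 90.7 TPM, PPIA at 1514 ± 18.1 TPM and RPLP0 at 1476 ± 61.2 TPM.

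The proliferation, G1, interferon and unfolded protein lists did not pass the test against random lists. All but the interferon list had medians above the 8.07 TPM of protein-coding genes. All 20 proliferation genes were detected (median 29.4 TPM, adjusted permutation p = 0.152), with PCNA at 100.2 ± 12.8 TPM, MCM3 at 92.0 ± 20.2 TPM, MCM7 at 66.6 ± 12.5 TPM and TOP2A at 52.5 ± 10.6 TPM. G1 regulators (33.9 TPM, adjusted permutation p = 0.153) were led by CCND1, CDK4 at 139 ± 14.6 TPM and the inhibitor genes CDKN1B at 133 ± 4.14 TPM and CDKN1A at 82.2 ± 37.1 TPM. Interferon response genes (6.19 TPM, adjusted permutation p = 0.766) included BST2 at 309 ± 17.1 TPM, ISG15 at 37.4 ± 12.4 TPM and IFI6 at 31.3 ± 10.6 TPM. Unfolded protein and amino acid stress genes (29.3 TPM, adjusted permutation p = 0.236) included ATF4 at 542 ± 3.39 TPM, the chaperone gene HSPA5 at 402 ± 54.3 TPM, HERPUD1 at 209 ± 33.7 TPM and TRIB3 at 155 ± 10.8 TPM. The small nuclear, 7SK and 7SL RNA genes, which poly-A selection largely removes, took 0.00602 ± 0.00168% of counts, with RN7SL1 at 185 ± 42.6 TPM, RN7SK at 160 ± 57.3 TPM, RN7SL2 at 150 ± 41.7 TPM and RMRP at 14.3 ± 4.29 TPM. RN7SL1 and RN7SL2 share sequence, so the division between them is uncertain.

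Of 27 lists tested for level, 8 lay above and 2 below random lists, with 2e-04 the smallest p that 10000 random lists can give.

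**Figure D2:**
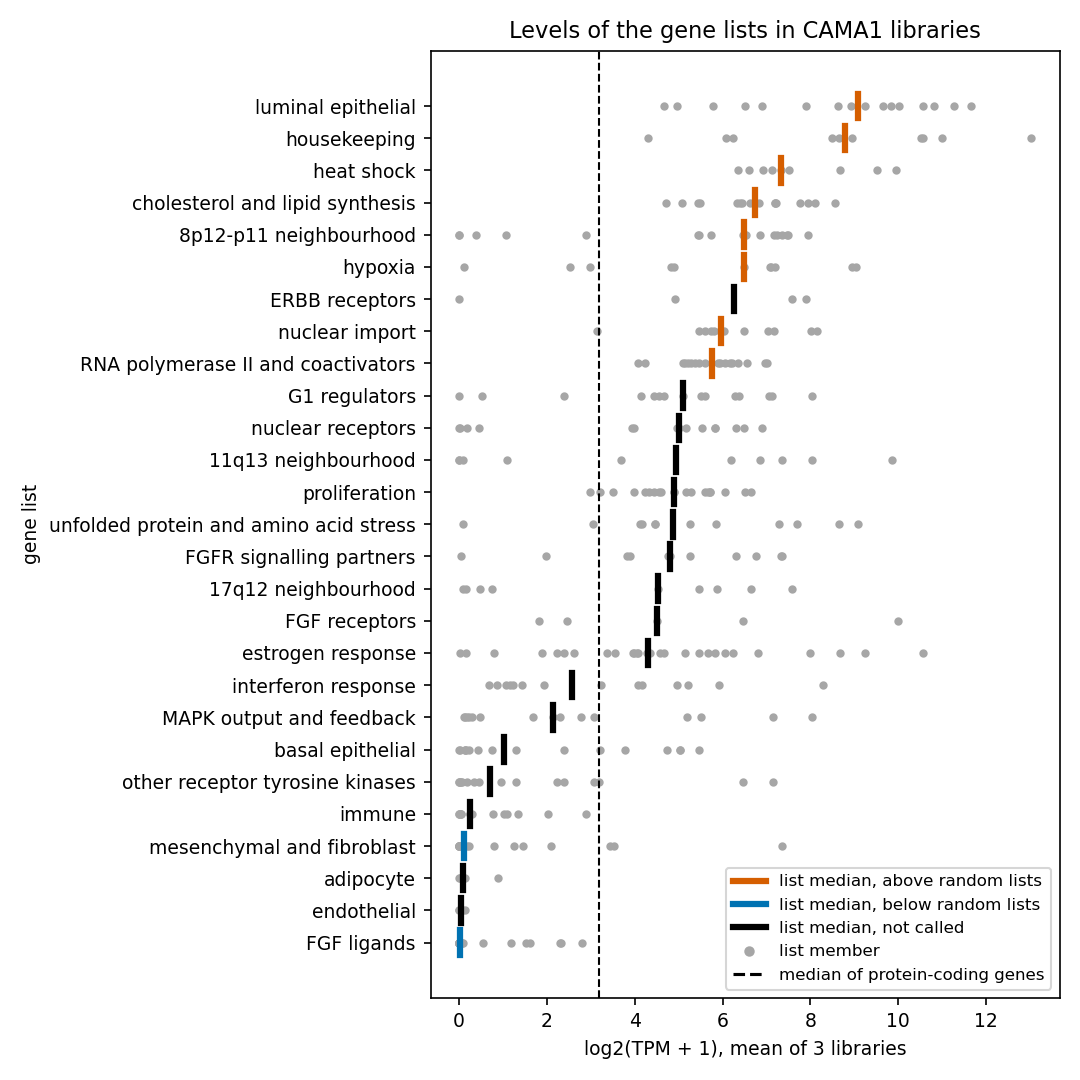
Levels of the members of each gene list as log2(TPM + 1), mean of 3 libraries, with a point per gene, the median of each list marked (orange above and blue below random lists, black not passing) and the median of all protein-coding genes (3.17) as a line. The luminal list, at a median of 9.08, lay above that line and the FGF ligands, at 0.02, lay below it.

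The genes around FGFR1 on 8p12-p11, the segment that is amplified together with it in some breast cancers, were mostly highly expressed. Of the 19 protein-coding genes from ZNF703 to TACC1 (chromosome 8, 37695751 to 38853028), 17 were detected and 14 reached 10 TPM. LSM1 stood at 245 ± 12.6 TPM, PPAPDC1B at 180 ± 22.6 TPM, ERLIN2 at 176 ± 5.09 TPM, the translation repressor gene EIF4EBP1 at 163 ± 9.92 TPM, ASH2L at 150 ± 8.14 TPM and DDHD2 at 142 ± 8.48 TPM, all above FGFR1 (88.0 ± 3.86 TPM), while GOT1L1 and ADRB3 had no counts. The median of the run was 89.3 TPM, and 0.529% of 18516 runs of 19 consecutive genes had a median as high; the share was 1.41% among runs of detected genes and 1.92% on the mean of the run. As a list, the same genes lay above random lists (adjusted permutation p = 0.0018). DNA copy number was not analysed here.

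Among all protein-coding genes, the 11q13 and 17q12 runs, around CCND1 and ERBB2, stood less far from other runs than 8p12-p11. The 10 genes from CCND1 to SHANK2 (chromosome 11, 69641105 to 71224796) had a median of 42.3 TPM, and 16.2% of 18723 runs were as high; CTTN, which codes for cortactin, stood at 933 ± 63.3 TPM, PPFIA1 at 163 ± 10.8 TPM, FADD at 114 ± 3.95 TPM, ORAOV1 at 72.6 ± 3.97 TPM and SHANK2 at 11.9 ± 0.842 TPM. When runs held detected genes only, 1.85% were as high as the 11q13 run, close to the 1.41% of 8p12-p11, and 18.4% as high as the 17q12 run. On CPM the 11q13 share was 5.98%. The 9 genes from PPP1R1B to IKZF3 (chromosome 17, 39626924 to 39864188) had a median of 22.0 TPM, and 27.8% of 18746 runs were as high. Next to ERBB2, MIEN1 stood at 99.9 ± 10.3 TPM, STARD3 at 57.9 ± 0.921 TPM, PGAP3 at 43.1 ± 0.944 TPM, GRB7 at 22.0 ± 0.473 TPM and TCAP at 0.707 ± 0.277 TPM. As lists, neither passed the test (adjusted permutation p = 0.236 for 11q13 and 0.448 for 17q12).

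**Figure D3:**
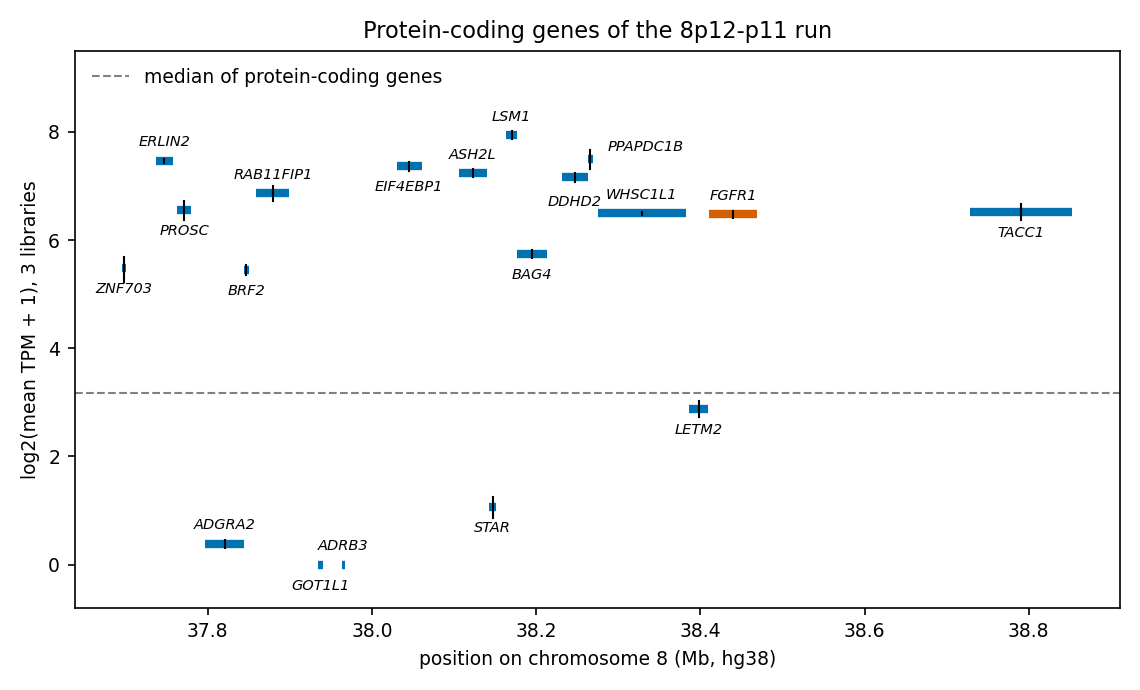
Protein-coding genes of the 8p12-p11 run by position on chromosome 8 (x axis, megabases, hg38) and level (y axis, log2 of mean TPM + 1 over 3 libraries); each horizontal bar spans a gene, black lines are ± SD, and FGFR1 is orange. FGFR1, at 88.0 TPM, lay near the run's median of 89.3 TPM.

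The 10 genes that varied most between replicates were early response genes and HES1, all lowest in replicate 1, and 4 genes lowest in replicate 3. EGR1, an immediate early transcription factor gene, had 19.4, 466 and 487 CPM in replicates 1, 2 and 3, FOS 4.04, 80.4 and 64.5 CPM, and the orphan receptor gene NR4A1 10.5, 156 and 162 CPM. IER5 (11.9, 51.1 and 29.9 CPM), HES1 (50.2, 189 and 177 CPM) and the phosphatase gene DUSP1 (68.8, 240.4 and 194 CPM) were also lowest in replicate 1. Replicate 3 had the lowest values of the complement gene CFB (15.2, 15.9 and 3.39 CPM), TNFAIP2 (22.7, 20.9 and 6.97 CPM), the interferon-induced gene MX1 (15.3, 17.6 and 5.46 CPM) and SUSD3 (17.6, 19.1 and 6.81 CPM). These 10 genes had the largest coefficients of biological variation among genes at 10 CPM or above, from 30.7% for SUSD3 to 75.3% for EGR1, and edgeR negative binomial adjusted p-values from 6.8e-136 for EGR1 to 5.9e-07 for SUSD3.

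Of 14453 genes tested, 6018 (41.6%) varied between replicates beyond Poisson sampling and 190 (1.31%) beyond the trended negative binomial dispersion. The common coefficient of biological variation was 8.80%. Each of the 190 genes was assigned to the library farthest from the middle of its 3 values. Replicate 3 was that library for 99 lower and 67 higher genes, replicate 1 for 18 lower and 2 higher genes (RN7SK and SNORD83A), and replicate 2 for 4 higher genes (JUN, MYC, ZFP36 and SAT1) and 0 lower; apart from RN7SK these were named after their values were seen. Replicates 1 and 2 differed at 1182 genes beyond Poisson sampling, replicates 1 and 3 at 5450 and replicates 2 and 3 at 4742. Pearson r of log2 CPM across genes, which are not independent replicates, was 0.997, 0.992 and 0.994. Without replicate 3 the coefficient was 5.25% and 1174 genes varied. These tests compare libraries and not conditions.

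Proliferation and interferon response genes were lower in replicate 3 than in replicates 1 and 2. The 20 proliferation genes deviated from their means by 0.21, 0.13 and −0.34 log2 units in replicates 1, 2 and 3; 19 differed between libraries, or 20 adjusted over the list alone, and all 19 were lowest in replicate 3. Under the negative binomial test 5 differed, namely MKI67, MCM2, MCM3, MCM5 and RRM2. The 13 interferon response genes deviated by 0.33, 0.36 and −0.69, 12 differed (12 adjusted over the list alone), 11 of these were lowest in replicate 3, and 6 passed the negative binomial test: IFIT1, IFIT2, IFIT3, MX1, OAS2 and RSAD2. The list tests gave an adjusted permutation p of 8.67e-04 for both lists, from the smallest p that 10000 random lists can give (1e-04). Random lists hold genes picked singly, so any list whose members vary together can pass on ordinary variation between cultures. The members named here, and those of the lists that follow, were chosen after their values were seen, apart from the genes with levels given above.

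Estrogen response genes deviated by 0.07, 0.10 and −0.17 (adjusted permutation p = 0.0013); 16 of 25 differed (16 adjusted over the list alone), 10 lowest and 5 highest in replicate 3, and PGR, TFF1, CXCL12, ELOVL2 and MYBL1 passed the negative binomial test, all lower in replicate 3. G1 regulators deviated by 0.06, 0.08 and −0.14 (adjusted permutation p = 0.0234), and 11 of 14 differed (11 adjusted over the list alone). Among them CCNE2, CDKN2B and E2F1 passed the negative binomial test, as did CDKN1A, a cell cycle inhibitor gene that went the other way with 1492, 1703 and 3865 counts. Hypoxia genes deviated by −0.10, −0.02 and 0.12 (adjusted permutation p = 0.0401). Of 10 genes 8 differed (8 adjusted over the list alone), 5 highest and 3 lowest in replicate 3. VEGFA, NDRG1 and SLC2A1, which passed the negative binomial test, were higher in replicate 3, while ADM, PDK1 and EGLN3 were lowest there. NDRG1 had 4022, 4383 and 8548 counts and SLC2A1 4205, 4514 and 7545. The summed level of the mesenchymal and fibroblast markers was 199, 210.1 and 165 TPM in replicates 1 to 3, of which COL3A1 held 171, 182 and 137 TPM. Without replicate 3, which leaves replicates 1 and 2, the proliferation, interferon, estrogen response, G1 and hypoxia lists did not pass. Hypoxia also did not pass without replicate 1 (adjusted permutation p = 0.161), and on list medians neither it (0.170) nor estrogen response (0.126) passed.

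Within MAPK output and feedback, EGR1 and FOS were low in replicate 1 and carried the mean of the list, which deviated by −0.56, 0.43 and 0.13 in replicates 1, 2 and 3 (adjusted permutation p = 8.67e-04). Of 10 genes 6 differed (6 adjusted over the list alone), 4 of them lowest in replicate 1 and 2 lowest in replicate 3, and EGR1 and FOS alone passed the negative binomial test. The other 8 genes, an alternative chosen after seeing the data, did not share that direction: they deviated by 0.03, 0.16 and −0.18, with replicate 3 lowest (permutation p = 0.0175, not adjusted). The list's median, which deviated by 0.00, 0.27 and −0.04, did not either (adjusted permutation p = 0.00607). The small nuclear and 7SK/7SL RNA list was highest in replicate 1, with deviations of 0.42, −0.25 and −0.17 (adjusted permutation p = 0.0026). Its 5 tested genes were RN7SK, RN7SL1, RN7SL2, RMRP and RPPH1. RNU4-1, RNU4-2 and RNU5A-1 had at most 1 count in each library and were not tested. RN7SL1 and RN7SL2 share sequence and are not separate evidence. Of the 5 genes 4 differed (5 adjusted over the list alone), among them RN7SK with 740, 454.5 and 457 counts. Without replicate 1 this list did not pass (adjusted permutation p = 0.749).

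The other 19 of 26 lists did not pass, among them the luminal list (adjusted permutation p = 0.0647, and 0.0208 without replicate 3), the immune list (0.0670, and 0.0465 without replicate 2), heat shock genes (0.389, and 0.0442 without replicate 3), the FGF receptors (0.803) and the 8p12-p11 genes (0.803). Endothelial, adipocyte and mitochondrially encoded genes had fewer than 3 members to test.

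**Figure D4:**
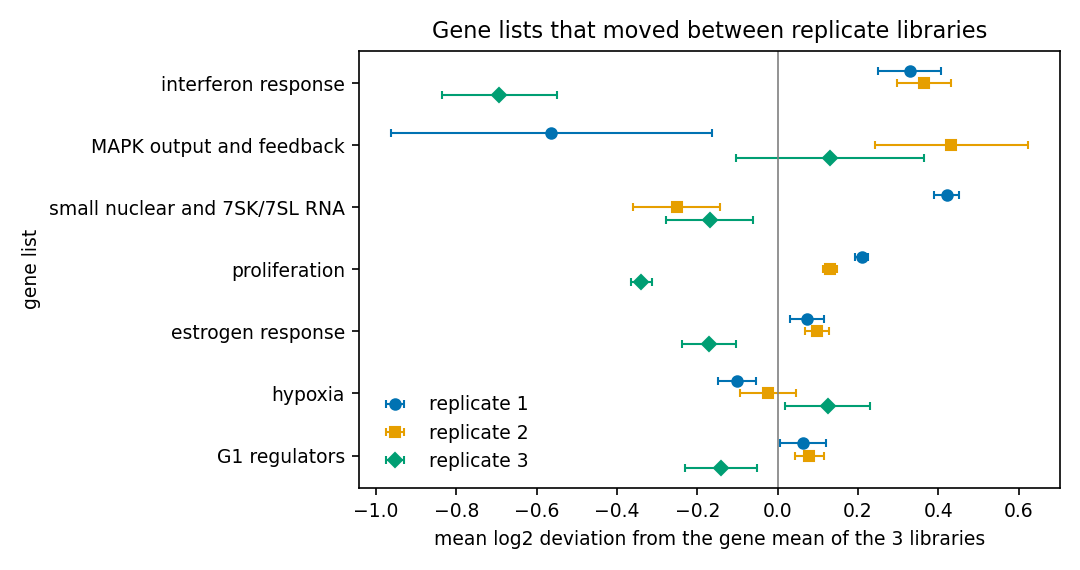
Mean deviation of the 7 gene lists that passed the test from their genes' means over the 3 libraries, in log2 CPM, with a point per replicate and bars for ± SE over the genes of the list. The interferon list reached −0.69 in replicate 3 and the MAPK list −0.56 in replicate 1, where its value rests on EGR1 and FOS.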

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

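The tests of gene length, of a single library, of depth and of other cell types were chosen only after the result was seen. The tests of shared reads, other immediate early genes, short-lived transcripts, GC content and p53 targets were set before their values were seen, apart from EGR3 and ATF3.

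Genes of the MTRNR2L family, nuclear copies of mitochondrial ribosomal RNA, took 0.494% of counts, above the limit of 3 counts that an absent signal allows, although no mitochondrially encoded gene had a value in the table. Ribosomal RNA genes took 0.469% of counts in libraries made from poly-A RNA, also above that limit.

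FGFR4 exceeded FGFR1 in each of the 3 libraries, 9.85, 10.7 and 14.6 times on TPM. The tables argue against gene length, since the log2 ratio without division by length was still 2.55 ± 0.30 (SD, n = 3). The lowest log2 ratio of TPM in a single library was 3.30, so the check of a single library restates the result. Shared reads are argued against as well: 0.526% of 5325 windows of 50 bases in FGFR4 transcripts occurred in transcripts of other genes, and FGFR4 had whole counts in 3 libraries and no gene overlapping its exons. No biological explanation was tested, because the design has 1 group.

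EGR1 and FOS were lower in replicate 1 than in the mean of replicates 2 and 3, with differences of −4.61 and −4.13 log2 units. The difference was first seen on scaled values, so these values, scaled for depth, restate it. Depth is argued against by the totals, 26473939 counts in replicate 1 and 26592335 in replicate 2, beside 518 and 12370 counts of EGR1. An effect on EGR1 and FOS alone is argued against because 19 other immediate early genes had a median difference of −0.73 ± 0.15 (SE over genes), with 17 of them lower. A loss of short-lived transcripts cannot be told apart from other causes. The median of 20 such transcripts, −0.11 ± 0.13 with 12 lower, fell between the bounds set for and against it. Yet only 0.03% of random lists matched on mean expression had a lower median in replicate 1, so the value is not near that of random lists. The 5 tested genes of the small nuclear and 7SK/7SL RNA list, among them RN7SL1 and RN7SL2 with shared sequence, had their highest mean in the same library. That mean deviation was 0.42 (adjusted permutation p = 0.0026), so a difference in RNA or in poly-A selection stays open, untested. The immediate early genes respond within minutes to medium change or serum, so a difference in handling before harvest may have set replicate 1 apart; nothing here records handling, and no biological explanation was tested.

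Proliferation and interferon response genes were lower in replicate 3 than in the mean of the other libraries, by means of −0.51 and −1.04 log2 units. A trend with GC content or gene length is argued against, since its removal left −0.51 ± 0.0427 (SE over genes) for proliferation and −1.06 for interferon response. Immune, endothelial and adipose cells are argued against, since their summed markers changed by 0.0235 TPM in replicate 3. With fibroblast markers included the change was −39.1 TPM, which rests on COL3A1 at 171, 182 and 137 TPM in replicates 1 to 3. COL1A2, DCN and LUM had 0 counts in each library. The fall of 1 gene does not decide on fibroblasts, and epithelial cells of another kind were not tested. A p53 response is argued against by the mean of 14 p53 targets, −0.18 ± 0.0837, although CDKN1A was higher by 1.09. For the proliferation list alone, a smaller share of dividing cells in replicate 3, for instance in a denser culture, is a candidate explanation that stays open. No candidate is given for the larger fall of the interferon list, and beyond the p53 response no biological explanation was tested.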

How the results depend on the processing

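Alternatives chosen only after the result was seen were exon lengths on the main chromosome, whole counts, removal of the GC and length trend, the MAPK list without EGR1 and FOS, and a dispersion estimate without the 190 genes past the negative binomial test (7.32% against 8.80%). On CPM the log2 ratio of FGFR1 was 4.78 over FGFR3, −2.55 over FGFR4 and 2.97 over FGFRL1, and that of ESR1 was 0.14 over PGR, −2.32 over ERBB2 and 6.74 over ESR2, the change being that of the genes' lengths. With a pseudocount of 1 TPM, which shrinks ratios to low genes, FGFR1 over FGFR3 was 4.01 and ESR1 over ESR2 4.5. Lists below the transcriptome numbered 1 in place of 2 with a background of detected genes and 1 on CPM. Against detected genes that list was the other receptor tyrosine kinases, and neither the FGF ligand nor the mesenchymal list passed. Lists above numbered 6 in place of 8 with that background and 9 on CPM. Among runs of detected genes 1.85% were as high as 11q13 and 1.41% as high as 8p12-p11 (1.92% on the mean of the run). The negative binomial test called 190 genes in place of 6018, since it allows for the typical spread between replicates. With each replicate left out, 4 to 8 lists deviated, 1174 to 5435 genes differed and the coefficient of biological variation was 5.25% to 11.4%, the lower ends without replicate 3; the cause was not tested. The luminal list's deviation passed with no filter (adjusted permutation p = 0.0388), on medians (0.00416) and without replicate 3 (0.0208), while hypoxia did not pass under 5 alternatives (0.0520 to 0.183). Exon lengths on the main chromosome moved 25 values of the 134 named genes by more than 1 SD. None of the 27 lists tested for level changed its test result. Of these genes CFB (1.72 to 11.3 TPM) and DDR1 moved by over 1.5 times. Other list members did so too, for instance HSPA1A, HSPA1B, B2M (399 to 774 TPM) and CDK7 (47.6 to 92.3 TPM). Among list medians, heat shock did (160 to 395 TPM). TPM without mitochondrially encoded genes was not run because the table had none, and endothelial and adipocyte lists had too few detected members for a value against detected genes. The MAPK list, low in replicate 1 by its mean, turned on its median (range 0.31) and with EGR1 and FOS left out (range 0.34), because these genes carry the mean. No paired analysis was possible because there is 1 group. Depth limits what can be said of genes at 3 or fewer counts, such as EGFR and most FGF ligands.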

Other observations

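The lists of milk fat and apocrine genes, immediate early genes, short-lived transcripts and p53 targets, and their tests, were chosen after other results had been seen.

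Among milk fat and apocrine genes, FABP7 at 6124 TPM was accompanied by the secretoglobin gene SCGB2A2, which codes for mammaglobin, at 134 ± 36.8 TPM, SCGB1D2 at 25.7 ± 7.35 TPM and AZGP1 at 14.7 ± 0.927 TPM (SD, n = 3). The apocrine marker PIP and the casein genes CSN2 and CSN3 had 0 counts. The mean of the 7 tested genes of this list did not pass the test between libraries (range 0.09, adjusted permutation p = 0.712 over 5 added lists). Of these genes 4 differed beyond Poisson sampling and 1, SCGB2A2 with 785, 776 and 543 counts, beyond the negative binomial dispersion (edgeR negative binomial adjusted p = 0.0211).

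Immediate early genes had a range between libraries of 0.99 log2 units (adjusted permutation p = 5e-04, from the smallest p that 10000 lists can give, 1e-04), and 16 of 19 differed. JUNB had 1652, 2750 and 3474 counts, IER2 1501, 4147 and 4659, and FOSB 40, 214 and 251. Short-lived transcripts had a range of 0.23 (adjusted permutation p = 0.00825), and p53 targets one of 0.19 (adjusted permutation p = 0.0418).

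Members of the MAPK output and feedback list, which did not pass the test for level (adjusted permutation p = 0.65), ranged widely. CCND1 stood at 263 TPM, SPRED2 at 44.2 TPM and EGR1 at 16.7, 395 and 402 TPM in replicates 1 to 3. Others that FGF receptor signalling is known to induce, picked after their values were seen, were low. ETV4 had 6, 2 and 4 counts, ETV5 7, 14 and 9, SPRY2 4, 1 and 2 and SPRY4 9, 9 and 12, and DUSP6 stood at 3.45 ± 0.971 TPM. COL1A2, whose product joins that of COL1A1 in collagen fibres, had 0 counts, while COL3A1 stood at 163 TPM.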
